A study of Mus musculus with 12 samples.

How the data were processed

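Gene expression was measured in regulatory T cells (Tregs) that had been sorted from mouse spleen by their CD4 and high CD25. Per the labels, cells bearing CD19, CD8a, CD11b, CD11c or NK1.1 were excluded on a MoFlo sorter, RNA was extracted with TRIzol, and all mice were 8 weeks old, female and of B6 background. The 12 arrays formed 6 groups of 2, a mutant and a wildtype group in each of 3 lines: Xbp1, Eos (the product of Ikzf4) and Gata1. The labels call all 3 alterations knockouts, while the series description says mutant or knockout, so "mutant" is used here for all 3 lines. The labels do not say that the 2 arrays of a group came from separate animals, so the p-values measure the spread between these samples, which could be technical in part. Every array was assigned to a group.

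The deposited values were probe set intensities on a linear scale, made by the authors with Affymetrix Power Tools and RMA per the submitters' processing notes, which give neither versions nor which arrays were normalised together. Labelling used the Affymetrix whole-transcript terminal labelling kit. The median intensity per array ran from 82.7 to 93.4. The number of arrays limits the precision. Of 24922 probe sets, 21425 carried 1 gene symbol, 1399 carried several and 2098 carried none. Gene IDs of 21347 probe sets with 1 symbol were found in a gene table of the assembly GRCm38.p6, which was used for current names and for the order of genes along chromosomes. For each of 19752 genes, the probe set with the highest mean was kept. Genes whose mean over the 12 arrays lay at or above the 40th percentile (5.97 on the log2 scale) were tested, which left 11851 genes.

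The intensities were log2 transformed and used without further normalisation. A linear model with 6 group means was fitted in limma 3.58.1 under R 4.3.3, with moderated variances, 6 residual degrees of freedom and 5.48 prior degrees of freedom. The contrasts were mutant minus wildtype in each line, the mean of these 3 effects, the 3 differences between the effects, and an F test over the 3 wildtype groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Counts at an unadjusted p under 0.05 are given too. A share near 0.05 arises by chance where no gene changes, so counts at or below it are no sign of further changes. Standard errors (SE) are those of the limma fit, and each group mean rests on 2 arrays. The variance of a gene is pooled over the 6 groups, so its SE is the same in each line. For Foxp3 it was 0.16 in all 3 lines, with wildtype SDs of 0.36, 0.006 and 0.04 in the Xbp1, Eos and Gata1 lines. The spread of the Xbp1 line thus enters the SE and p of the other lines. With 2 arrays against 2, the smallest p that an exact two-sided permutation test can give is 0.333, so no single value was tested that way.

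Design, contrasts, lists, naming rule and most alternatives were fixed before the data were examined. The rule for naming genes took the targeted gene, 6 core Treg genes (Foxp3, Il2ra, Ctla4, Ikzf2, Tnfrsf18 and Itgae) and up to 12 called genes each way. Where fewer than 10 passed on a side, that side was filled to 10 with the genes of largest change among those at an unadjusted p under 0.01 whose mutant and wildtype arrays did not overlap. In each list described, up to 4 members with the largest change were to be named. For the wildtype groups the 10 genes of widest range were named. Predicted genes, histones, large receptor families and RNAs with symbols in Snor, Mir or n-R5 were counted but not named. The names of Olfr373, of genes called with a replicate block outside the filled sides, and of genes named in the closing paragraphs were chosen after their values were seen.

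There were 19 gene lists, written from general knowledge and not derived from these samples or from a measured signature. These were genes higher in Tregs, genes lower in Tregs, candidate Foxp3 cofactors, the unfolded protein response with Xbp1 targets, effector Treg genes, naive T cell genes, helper lineage genes with cytokines, cell cycle, type I interferon response, immediate early genes, IL-2 and STAT5 response, glycolysis, cholesterol synthesis, T cell identity, and markers of B cells, plasma cells, CD8 T and NK cells, myeloid and dendritic cells, and erythroid cells and platelets. The genes higher and lower in Tregs are called the Treg signature here. Lists can share members. Members without a probe set of their symbol alone were not tested, among them Tcf7 and Sell of the genes lower in Tregs and the globins of the erythroid list. Members below the level filter were not tested either, among them Pde3b and Il2. Each list was tested against the other genes with camera in limma at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Adjusted p-values cover the 19 lists and 3 lines together, while the mean effect and the differences between lines formed families of their own. Since camera compares a list with the other genes, its direction can differ from the sign of the list's median where all genes are shifted. Fry in limma, which asks whether a list moves on balance one way or changes in either direction, was run as an alternative.

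The arrays of each group are numbered 1 and 2, and the 2 unnumbered Xbp1 arrays were taken as number 1. Numbers were to be treated as pairing if the deviations of mutant and wildtype arrays of the same number correlated above 0.1. They did, with correlations across genes of 0.721 in the Xbp1 line, 0.136 in the Eos line and 0.123 in the Gata1 line. Results of a fit with a replicate block (6 pairs, 3 residual degrees of freedom) are therefore given beside the results without it where the call changes. The gene counts of both fits had been seen when this criterion was applied. The labels do not say what the numbers mark, and the correlations in the Eos and Gata1 lines lay only a little above 0.1. Pairing is therefore weakly grounded in these lines, and blocked results and values within pairs depend on it.

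Alternatives were no level filter or one at the 60th percentile, every probe set as its own row, median centring, repeated quantile or cyclic loess normalisation, an intensity trend with robust variances, array weights, only the 4 arrays of a line, an adjusted p under 0.1, an unadjusted p under 0.05 with a 1.5-fold change, the replicate block, and leaving out each array in turn. A group left with 1 array was assumed to vary like the other groups. Leaving the Xbp1 line out of the fit, blocking in that line alone, blocking without chosen arrays, and leaving out each array of a line for the lists outside the Treg signature were added after the data were seen. Where neither fit called a gene or list, it was counted as unaltered whatever its sign.

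The procedure was tested on simulated data with the same design, in which 200 of 11851 genes were changed. Of 50 genes changed 1.5-fold, 21, 20 and 15 were recovered in the 3 lines without a block, and of 50 changed 2-fold, 46, 49 and 47. False calls numbered 11, 12 and 9. With so many changed genes the adjusted threshold is more lenient than where few change, so these shares do not carry over to lines with few calls. The simulated noise had the same spread per gene in all lines and, without a block, no pairs. In the data, the SD across genes of array 1 minus array 2 was 0.42 in mutants and 0.34 in wildtypes of the Xbp1 line. It was 0.22 and 0.16 in the Eos line and 0.19 and 0.20 in the Gata1 line. The shares therefore do not carry over to the Xbp1 line either. In lists of 30 unshifted genes with a correlation of 0.2, camera with the preset correlation gave p under 0.05 in 36% of draws, against 4% with the estimated correlation.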

Results

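Tregs from the spleens of 3 mouse lines were profiled on 12 arrays, with 2 mutant and 2 wildtype arrays per line. The question in the series description was how the loss or mutation of candidate Foxp3 cofactors (Xbp1, Eos or Gata1) bears on the transcripts that set Tregs apart from other T cells. Foxp3 is the transcription factor that defines Tregs. Expression values are log2 intensities of probe sets, and changes are log2 fold changes (mutant over wildtype) with their limma SE, with n = 2 arrays per group. The arrays of a group correlated with each other at 0.980 to 0.995. Median array levels of mutants lay 0.05, 0.02 and -0.03 log2 from those of their wildtypes in the Xbp1, Eos and Gata1 lines, and the Eos wildtype level lay 0.14 above the Xbp1 wildtype level.

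Of the 3 targeted transcripts, that of Ikzf4 passed in its own line, with the replicate block. Ikzf4, which encodes the zinc finger protein Eos, was at 7.25 ± 0.10 (SD, n = 2) in mutants and 8.21 ± 0.10 in wildtypes, a change of -0.96 ± 0.15. Its limma adjusted p was 0.604 over all genes without the replicate block and 0.00726 with it, and it passed when adjusted over the list alone in both lists that hold it. Xbp1, a transcription factor of the unfolded protein response, changed by -0.45 ± 0.22 in its own line (adjusted p = 0.963, or 0.190 with the block). Xbp1 mutant arrays were at 8.56 and 8.98 and wildtype arrays at 8.82 and 9.61. These ranges overlapped, while the mutant was lower within both same-numbered pairs (-0.25 and -0.64). With 1 array left out the change of Xbp1 ran from -0.85 (without wildtype array 1) to -0.05 (without wildtype array 2), while that of Ikzf4 in the Eos line ran from -1.03 to -0.89. Gata1, best known as an erythroid and megakaryocytic transcription factor, changed by -0.10 ± 0.18 in its own line (adjusted p = 0.964, or 0.785 with the block). The 3 probe sets do not show which part of each gene was altered.

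**Figure D1:**
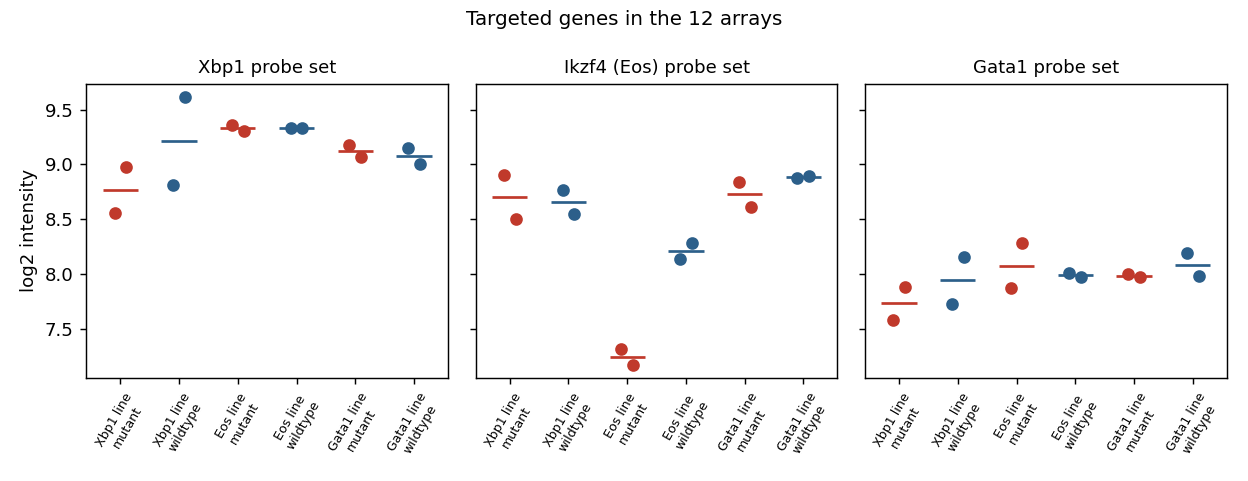
Log2 intensity of the Xbp1, Ikzf4 (Eos) and Gata1 probe sets in each of the 12 arrays (points, red for mutant and blue for wildtype, 2 per group), with group means as bars. Ikzf4 mutant arrays of the Eos line lie apart from all others, near 7.25, while the mutant and wildtype ranges of Xbp1 and Gata1 overlap.

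In the sorted samples of Xbp1 mutants, transcripts of B cells and of MHC class II antigen presentation were higher than in those of wildtype littermates. All 17 tested B cell markers were higher, with a median change of 0.63, and 13 passed when adjusted over the list alone, while 0 passed over all genes. Among them were Cd79a, a chain of the B cell receptor complex (1.07 ± 0.24), the class II chains H2-Ab1 (0.96 ± 0.14) and H2-Aa (0.87 ± 0.17), and Ly6d (0.96 ± 0.28). Camera gave an adjusted p of 4.59e-24 for the list, and an adjusted p = 0.383 with an estimated correlation. The medians were 0.54 and 0.83 within the same-numbered pairs, 0.37 without mutant array 2 and 0.87 without mutant array 1. The 11 tested myeloid and dendritic cell markers were also all higher, with a median of 0.38, and 2 passed when adjusted over the list alone: the neutrophil protein S100a9 (0.96 ± 0.29) and the macrophage receptor Csf1r (0.55). Camera gave this list an adjusted p of 2.37e-06, and an adjusted p = 0.829 with an estimated correlation. Its medians within the pairs were 0.63 and 0.13, as the mean of the list was 7.22 in wildtype array 1 and 7.77 to 7.97 in the other 3 arrays, and without that array the median was 0.22 (adjusted p = 0.0290). The sort had excluded cells with CD19, CD11b or CD11c. Both lists were tested in part. Of the B cell list, Cd19 and Ighd had no probe set of their symbol alone, and Ms4a1, Blnk, Fcer2a and Ebf1 lay below the level filter. Of the myeloid list, Itgam, Itgax, Cd14 and Adgre1, among others, lay below it.

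No gene passed over all genes in the Xbp1 line in limma (0 of 11851), and 512 (4.3%) had an unadjusted p under 0.05. With the replicate block 19 passed, 13 higher and 6 lower. Mid1, which encodes a microtubule-associated ubiquitin ligase, showed the largest change, at -1.79 ± 0.24 (adjusted p = 0.124, or 6.32e-07 with the block). The genes that rose with the block included H2-Ab1 and Alox5ap, a protein of leukotriene synthesis (0.98 ± 0.16), each with a blocked adjusted p of 0.00116. Ly6d (0.00436), H2-Aa (0.0108), the class II invariant chain Cd74 (0.81, 0.0217), Ly86 (1.21 ± 0.35, 0.0264) and Cd79a (0.0342) also rose, with blocked adjusted p in parentheses. Gdap10 (-0.74), Zfp709 (-0.72) and Pgpep1l (-0.64) fell with the block, at 0.0264, 0.0399 and 0.0454. Lcn2 (0.98), S100a9 and Cd24a (0.80) did not pass either fit, nor did Zfp52 (-0.61), the chemokine receptor Ccr9 (-0.57), Dcaf17 (-0.56), AB010352 (-0.55), the interferon-induced Ifit2 (-0.54) and Boll (-0.54). Without the block, leaving out mutant array 1 gave 15 genes, leaving out mutant array 2 gave 7 and leaving out wildtype array 2 gave 1.

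In the Treg signature of the Xbp1 line, of 46 tested genes higher in Tregs, 24 were higher and 22 lower in mutants, with a median of 0.01, a mean of -0.02 and a camera adjusted p of 0.773 in the lower direction. None of the core genes passed: Foxp3 changed by 0.08 ± 0.16, the IL-2 receptor chain Il2ra by -0.25 ± 0.16, the inhibitory receptor Ctla4 by -0.25 ± 0.25, the Ikaros family factor Ikzf2 by -0.33 ± 0.17, Tnfrsf18 by -0.13 ± 0.14 and the integrin chain Itgae by -0.18 ± 0.25. Of 27 genes lower in Tregs than in other T cells, 23 were lower still in mutants, with a median of -0.13 and a camera adjusted p of 0.00198, or 0.929 with an estimated correlation. Examples were Themis (-0.49), St8sia1 (-0.40), Ms4a4c (-0.35) and the transcription factor Lef1 (-0.32), of which none passed alone. Naive T cell genes were lower in 16 of 20, with a median of -0.12 and an adjusted p of 0.0023, or 0.929 with an estimated correlation, led by Bcl2 (-0.45) and Klf3 (-0.37). These lists share members such as Lef1, so they are not separate results: 10 of the 27 genes lower in Tregs and 12 of the 20 naive genes are in another list. Single arrays set the size of both changes. For the genes lower in Tregs the median was -0.03 (camera adjusted p = 0.543) without mutant array 1, -0.05 (0.0727) without wildtype array 2, and -0.30 without mutant array 2. For the naive genes it was -0.05 (0.206), -0.08 (0.0727) and -0.23 without the same arrays, and -0.26 without wildtype array 1.

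Genes of the unfolded protein response, the pathway in which Xbp1 acts, did not pass as a list in the Xbp1 line. Of 48 tested, 27 were higher and 21 lower, with a median of 0.02 and a camera adjusted p of 0.846. The median was -0.10 without wildtype array 1 and 0.10 without wildtype array 2, so a small shift either way is not excluded. Sec61b (0.24), Ddost (0.22), Edem1 (-0.22) and Creld2 (0.20) changed most after Xbp1 itself, and 0 passed when adjusted over the list alone. Cell cycle genes were higher in 17 of 22 (median 0.10, adjusted p = 0.0123), glycolysis genes in 13 of 14 (0.12, 0.0489) and erythroid and platelet markers in 10 of 11 (0.17, 0.0105). With an estimated correlation their adjusted p were 0.929, 0.929 and 0.829, and 0 members of the 3 lists passed when adjusted over the list alone. Single arrays carried 2 of these lists. The mean of the glycolysis list was 8.52 in wildtype array 1 and 8.76 to 8.93 in the other 3 arrays, and without that array the median was -0.06 (adjusted p = 0.951). The mean of the erythroid list was 7.66 in mutant array 2 and 6.67 to 7.07 in the others, and without that array the median was -0.14 (adjusted p = 0.980). Within the pairs the medians were 0.17 and 0.03 for glycolysis and 0.15 and 0.22 for erythroid markers. The cell cycle list kept a median of 0.10 to 0.14 without any 1 array, but its adjusted p was 0.206 without mutant array 1, 0.0601 without mutant array 2 and 0.488 without wildtype array 2. Examples were the proliferation antigen Mki67 (0.38), the glycolytic enzyme Aldoa (0.37) and the red cell anion exchanger Slc4a1 (1.18 ± 0.62). Effector Treg genes were higher in 27 of 32, with a median of 0.14 and an adjusted p of 0.254, or 0.0199 with the block (0.860 with the block and an estimated correlation). Their pair medians were 0.16 and 0.02, and without the block the median was -0.10 without mutant array 1 and -0.01 without wildtype array 2. The other lists did not pass. Their medians and camera adjusted p were -0.08 and 0.157 for Foxp3 cofactors, 0.15 and 0.0928 for helper lineage genes, -0.08 and 0.0789 for the interferon response, 0.02 and 0.789 for immediate early genes, and -0.02 and 0.687 for the IL-2 response. They were 0.03 and 0.789 for cholesterol synthesis, 0.01 and 0.893 for T cell identity, 0.10 and 0.893 for plasma cell markers, and 0.01 and 0.919 for CD8 T and NK cell markers. In all 3 lines only 6 genes of each of the last 2 lists were tested, so their values say little about those cells. Of the 6 plasma cell genes, 4 are in another list. Jchain, Tnfrsf17, Ncr1 and Gzma, among others, lay below the level filter.

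**Figure D2:**
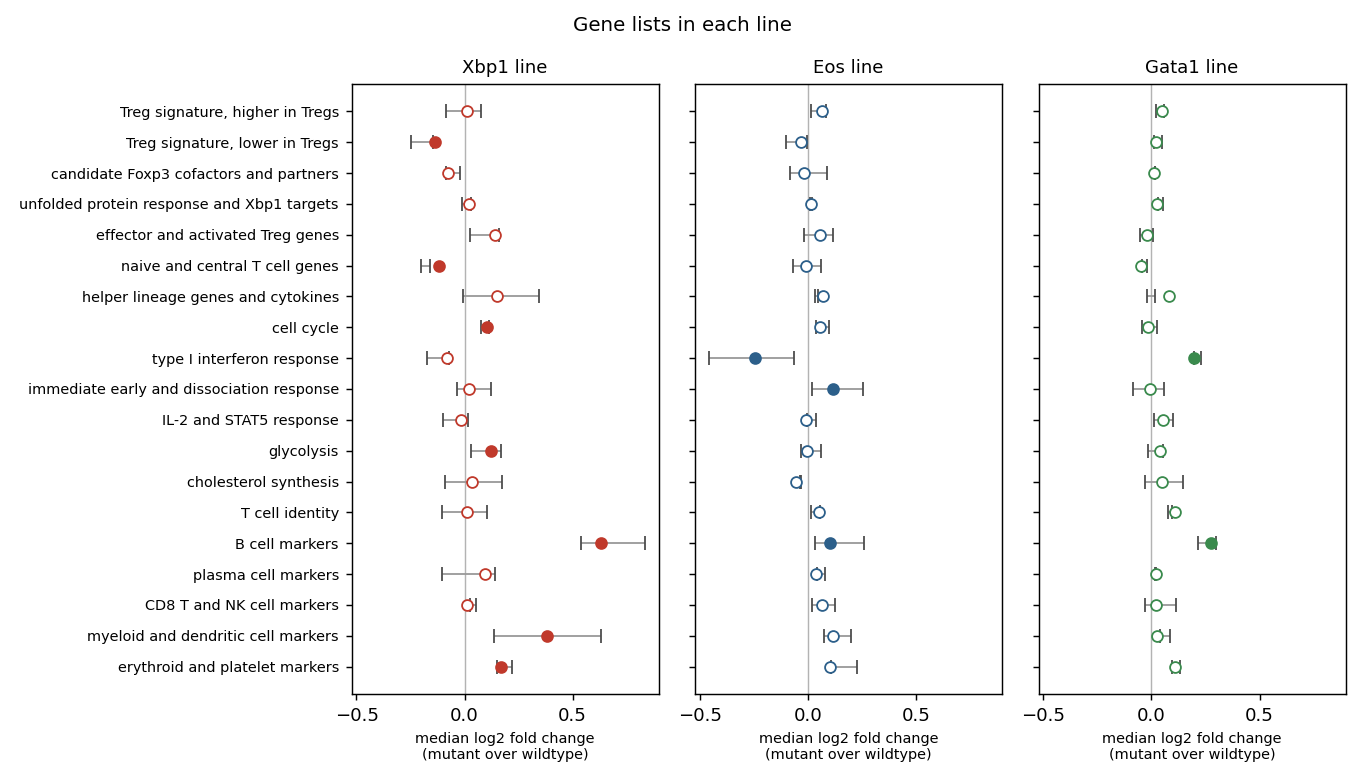
Median log2 fold change (mutant over wildtype, x axis) of the tested members of the 19 gene lists in each line. Circles are medians over both arrays per group, filled where camera with the preset correlation gave an adjusted p under 0.05, and ticks are the medians within each same-numbered pair. B cell markers reach 0.63 in the Xbp1 line, and the interferon list lies at -0.25 in the Eos line and 0.20 in the Gata1 line.

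In the Eos line, transcripts of the type I interferon response were lower in mutants than in wildtypes, mainly because 1 wildtype array was high. The mean of the list was 8.52 in wildtype array 1, 8.12 in wildtype array 2, and 8.07 and 8.03 in the mutants. Without wildtype array 1 the median change was -0.05 (camera adjusted p = 0.380). With all 4 arrays, of 25 tested members, 24 were lower, with a median of -0.25, among them the antiviral effector Ifit1 (-0.90 ± 0.36), the deubiquitinase Usp18 (-0.46), Rtp4 (-0.44) and Xaf1 (-0.42). Camera gave an adjusted p of 5.94e-10, and an adjusted p = 0.929 with an estimated correlation. No member passed when adjusted over the list alone (0 of 25), while 7 did with the replicate block. The median was -0.46 within pair 1 and -0.06 within pair 2. B cell markers were higher in 14 of 17 (median 0.10, adjusted p = 0.0123), with Ly6d and Cd180 at 0.41 each, and immediate early genes in 20 of 28 (0.12, 0.0471), with Jun at 0.41 and Junb at 0.38. Both had an adjusted p = 0.929 with an estimated correlation, and 0 members passed when adjusted over the list alone. The immediate early genes stood apart in mutant array 1, where their mean was 9.09, against 8.79 in mutant array 2 and 8.88 and 8.82 in wildtypes. Their medians within the pairs were 0.26 and 0.02, and without mutant array 1 the median was 0.00 (adjusted p = 0.109, tested direction down). For B cell markers the pair medians were 0.03 and 0.26, and the adjusted p was 0.156 without mutant array 2 and 0.302 without wildtype array 2. With the block, myeloid markers (median 0.12, adjusted p = 0.0351) and erythroid and platelet markers (0.10, 0.0145) passed too, and with an estimated correlation these adjusted p were 0.917 and 0.496. Without the block they were 0.0680 and 0.0698. The mean of the myeloid list was 7.50 in mutant array 2 and 7.17 to 7.22 in the other 3 arrays, with pair medians of 0.07 and 0.20, and without that array or the block the median was 0.03 (adjusted p = 0.619). The erythroid pair medians were 0.23 and 0.11, and without mutant array 1 or the block the median was 0.05 (0.802).

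**Figure D3:**
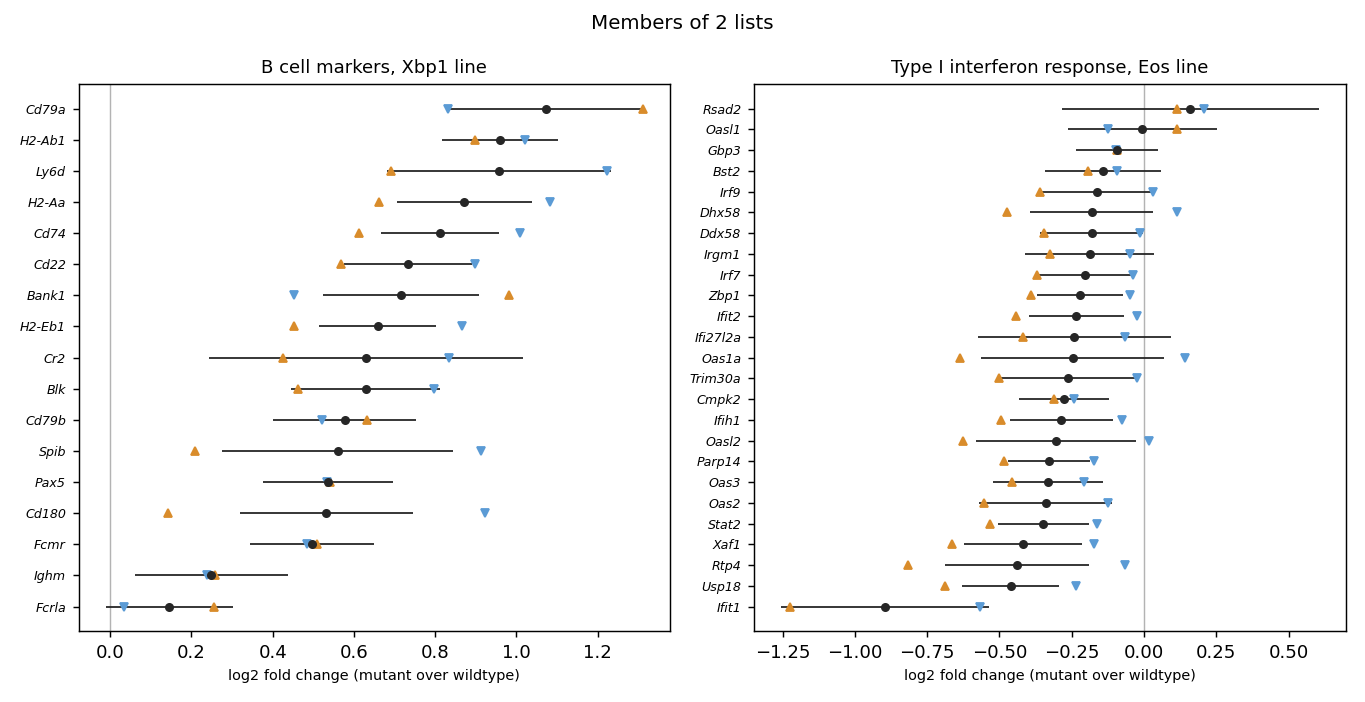
Log2 fold change (x axis) of each tested member of the B cell list in the Xbp1 line (left) and of the interferon list in the Eos line (right). Black points are the change (2 arrays per group) with its limma SE, whose variance is pooled over all groups. Upward triangles are pair 1 and downward triangles pair 2. All 17 B cell markers lie above 0, and 24 of 25 interferon genes lie below 0, farther in pair 1 than in pair 2.

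The Treg signature did not pass in either direction in the Eos line. Genes higher in Tregs were higher in 29 of 46 (median 0.06, camera adjusted p = 0.707), and genes lower in Tregs were lower in 15 of 27 (-0.03, 0.968). Of the first list only Ikzf4 passed when adjusted over the list alone. Its next members were the cytotoxic protease Gzmb (0.57), S100a6 (0.30) and Fgl2 (-0.28), and those of the second were the IL-7 receptor Il7r (-0.56), Id3 (-0.35), Cd40lg (0.34) and Sox4 (0.28). Foxp3 changed by 0.07 ± 0.16, Il2ra by -0.02 ± 0.16, Ctla4 by -0.15 ± 0.25, Ikzf2 by -0.12 ± 0.17, Tnfrsf18 by 0.09 ± 0.14 and Itgae by -0.21 ± 0.25. No gene passed over all genes in limma (0 of 11851), and 195 (1.6%) had an unadjusted p under 0.05. With the block 1 passed, Ikzf4. The next genes by the naming rule did not pass either fit. Cabp4 (0.59), the chemokine receptor-like Ccrl2 (0.47), Cltb (0.42), Crip2 (0.41) and Sec22b (0.39) were higher. Ddx60 (-0.61), Eif4a3 (-0.58), the interferon-inducible GTPase Iigp1 (-0.55), Gtpbp8 (-0.53), Oas1b (-0.51), Sap18 (-0.48), Teddm1b (-0.48), Brcc3 (-0.47) and Lce1e (-0.41) were lower.

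The other lists did not pass in the Eos line. Their medians and camera adjusted p were -0.02 and 0.789 for Foxp3 cofactors, 0.01 and 0.893 for the unfolded protein response, 0.06 and 0.443 for effector genes, and -0.01 and 0.968 for naive genes. They were 0.07 and 0.717 for helper lineage genes, 0.06 and 0.156 for cell cycle, -0.06 and 0.280 for cholesterol synthesis, 0.05 and 0.703 for T cell identity, 0.04 and 0.538 for plasma cell markers, and 0.07 and 0.765 for CD8 T and NK cell markers. The IL-2 response (median -0.01, mean 0.00, tested direction up) and glycolysis (-0.01, 0.02, tested direction down) were both at 0.968.

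In the Gata1 line, 3 genes passed over all genes in limma, with 610 (5.1%) at an unadjusted p under 0.05. Zhx2, a transcriptional repressor, was higher by 1.73 ± 0.14 (adjusted p = 8.43e-04), at 7.08 in wildtypes and 8.81 in mutants. Xbp1 and Eos wildtypes lay nearer to the Gata1 mutants than to the Gata1 wildtypes, as given in the closing paragraphs. An effect of the mutation was therefore not separated from a low wildtype level. Sfi1, a centrosomal protein, rose by 1.43 ± 0.15 (0.00607), and Olfr373, an olfactory receptor gene, fell by 1.58 ± 0.19 (0.0132). All 3 also passed with the replicate block, among 47 genes of which 37 rose and 10 fell. That count was 5 without both Gata1 arrays numbered 2, 23 with the block in the Xbp1 line only, and 83 with the block and the Xbp1 line left out. Those that rose with the block included the interferon-inducible Iigp1 (0.93, blocked adjusted p = 0.00334) and Ifit2 (0.73, 0.0178), AW112010 (0.93, 0.00114) and Ube2l6 (0.89, 0.0177). Myo3b (0.78), the drug efflux pump Abcb1a (0.75), the IL-18 receptor chain Il18r1 (0.74) and Gpn3 (0.73) rose as well, at 0.00873, 0.0104, 0.00969 and 0.0211. Arl2bp (-1.13, 1.99e-04), Trio (-1.07, 0.0024), Fzd6 (-0.63, 0.0211) and Rtf2 (-0.57, 0.0455) fell with the block. Rln3 (-0.58), Mmp14 (-0.52), Pabpc1l (-0.48), Mustn1 (-0.48), Tafa5 (-0.47) and Sh2b2 (-0.45) passed neither fit. Without the block, 1 gene passed when mutant array 2 or wildtype array 1 was left out and 2 when mutant array 1 was, and 23 passed when the Xbp1 line was left out of the fit.

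**Figure D4:**
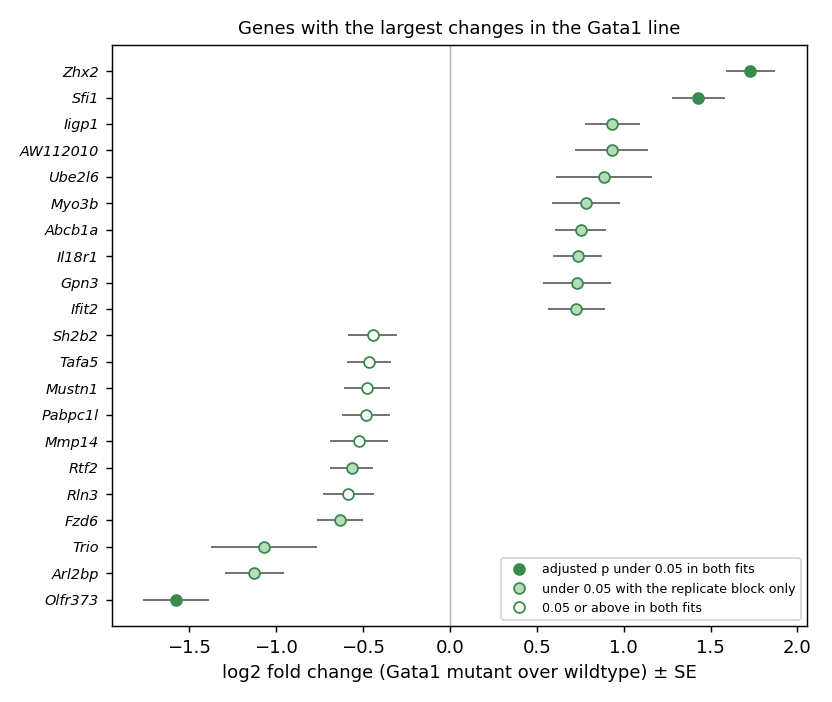
Log2 fold change with its SE (x axis, mutant over wildtype, 2 arrays per group) of the genes named in the Gata1 line. Dark points passed in both fits (Zhx2 at 1.73, Sfi1 at 1.43 and Olfr373 at -1.58), pale points with the replicate block only, and white points in neither.

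Interferon response genes were higher in Gata1 mutants, in 25 of 25 members, with a median of 0.20 and a camera adjusted p of 0.00176, or 0.929 with an estimated correlation. Ifit2 passed when adjusted over the list alone (1 of 25, or 5 with the block). Rsad2 was at 0.61, Rtp4 at 0.51 and Usp18 at 0.49. Gata1 wildtypes had the lowest mean of this list among the wildtype groups, at 7.88, against 8.33 and 8.32 in Xbp1 and Eos wildtypes. Gata1 mutants, at 8.12, still lay below those 2 group means, of which the Eos mean includes the high wildtype array 1. An effect of the mutation was therefore not separated from a low wildtype level in this line. B cell markers were higher in 15 of 17, with a median of 0.27 and an adjusted p of 0.00176, or 0.929 with an estimated correlation, led by the complement receptor Cr2 (1.12), Cd22 (0.58) and Cd79a (0.57), and 0 passed when adjusted over the list alone (5 with the block). The median change over all tested genes was 0.04 in this line. In the Treg signature, 27 of 46 genes higher in Tregs were higher (median 0.05, adjusted p = 0.893) and 15 of 27 genes lower in Tregs were higher (0.02, 0.946). Camera placed both in the lower direction, against the signs of their medians and means. Plagl1 (0.66), Ecm1 (-0.47) and Cd40lg (0.47) were the members farthest from 0, and none of the 3 passed when adjusted over the list alone. Foxp3 changed by -0.04 ± 0.16, Il2ra by -0.06 ± 0.16, Ctla4 by 0.34 ± 0.25, Ikzf2 by 0.08 ± 0.17, Tnfrsf18 by 0.05 ± 0.14 and Itgae by -0.36 ± 0.25, and 0 of these 6 passed.

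Among helper lineage genes in the Gata1 line, the chemokine receptor Cxcr5 (0.59) passed when adjusted over the list alone, while the list did not (median 0.08, adjusted p = 0.893). The other lists did not pass either. Their medians and camera adjusted p were 0.03 and 0.893 for the unfolded protein response, -0.02 and 0.703 for effector genes, -0.05 and 0.133 for naive genes, and -0.01 and 0.261 for immediate early genes. They were 0.05 and 0.789 for the IL-2 response, 0.05 and 0.889 for cholesterol synthesis, 0.11 and 0.528 for T cell identity, and 0.11 and 0.889 for erythroid and platelet markers. The erythroid list held the largest of these changes, in Slc4a1 (1.38 ± 0.62) and Car2 (1.05 ± 0.50). Camera placed 6 further lists in the lower direction: Foxp3 cofactors (median 0.01, 0.728), cell cycle (-0.02, 0.789, with a mean of 0.01), glycolysis (0.04, 0.789), plasma cell markers (0.02, 0.798), CD8 T and NK cell markers (0.02, 0.893), and myeloid markers (0.02, 0.946). With the exception of cell cycle, the medians of these 6 lists were above 0.

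The mean of the 3 mutant effects was tested too, although a large effect in 1 line can carry it. B cell markers were higher in 17 of 17, with a median of 0.33, and 13 passed when adjusted over the list alone, with a camera adjusted p of 6.69e-26 and an adjusted p = 0.113 with an estimated correlation. Myeloid markers (median 0.21, adjusted p = 3.01e-05) and erythroid and platelet markers (0.10, 0.00207) were higher, and naive genes were lower (-0.09, 7.37e-04). With an estimated correlation these adjusted p were 0.355, 0.289 and 0.452. Genes lower in Tregs (-0.07, 0.0258) and the interferon response (-0.05, 0.0279) were lower and cell cycle genes higher (0.05, 0.0258), with adjusted p of 0.633, 0.825 and 0.452 with an estimated correlation. The interferon value averages opposite changes. From wildtypes to mutants the list mean fell from 8.33 to 8.22 in the Xbp1 line and from 8.32 to 8.05 in the Eos line, where wildtype array 1 was high (8.52). It rose from 7.88 to 8.12 in the Gata1 line. No gene passed over all genes in limma (0 of 11851, with 319, or 2.7%, at an unadjusted p under 0.05). With the block 18 passed, 12 higher and 6 lower, among them H60b, a ligand of the NKG2D receptor (-0.58), Cr2 (0.54), Zhx2 (0.54), H2-Aa (0.50), Cd22 (0.48), Slc4a1 (1.00) and Mid1 (-0.48). Without the block, leaving out Xbp1 mutant array 1 gave 12 genes, and leaving out Xbp1 mutant array 2 or wildtype array 2 gave 1 each.

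The effects of the 3 mutants were compared gene by gene. Zhx2 was the gene that passed without the block, with an effect in the Gata1 line 1.84 above that in the Xbp1 line (adjusted p = 0.0167) and 1.73 above that in the Eos line (0.0305). Leaving out any 1 array of the Eos or Gata1 lines raised the latter above 0.05, and leaving out any 1 array of the Gata1 line did so for the former. With the block, 74 genes differed between the Gata1 and Xbp1 effects, 27 between the Gata1 and Eos effects and 1, Mid1 (1.96, 3.1e-05), between the Eos and Xbp1 effects. For the last comparison limma gave 0 genes without the block, with 165 (1.4%) at an unadjusted p under 0.05. For the Gata1 and Xbp1 effects the unblocked count was 2 without Xbp1 mutant array 1 or wildtype array 2, 6 without Xbp1 mutant array 2, and 0 without any 1 array of the Gata1 line. The interferon list had a median 0.42 higher in the Gata1 than in the Eos line, with a camera adjusted p of 6.51e-09 and an adjusted p = 0.939 with an estimated correlation, and it includes the high Eos wildtype array 1.

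Across the 11851 genes, which are not independent replicates, 3 correlations of log2 fold changes were computed. Pearson's r was 0.337 between the Xbp1 and Eos lines (Spearman's rho 0.319), -0.243 between Xbp1 and Gata1 (-0.265) and -0.221 between Eos and Gata1 (-0.226). The last was 0.0557 without Eos mutant array 1. The first was 0.145 without Xbp1 mutant array 1 and 0.085 without Eos mutant array 1, and the second was -0.09, -0.14 and -0.15 without Xbp1 mutant array 1, Xbp1 wildtype array 2 and Gata1 mutant array 2.

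The wildtype littermates of the 3 lines, which share 1 genotype label, were compared with each other. Of 11851 genes, 1717 passed the limma F test over the 3 wildtype groups, and 332 of them spanned at least 2-fold. The Gata1 wildtype group stood farthest from the others in 755 genes, the Xbp1 group in 664 and the Eos group in 298. Pairwise, 1430 genes differed between Gata1 and Xbp1 wildtypes, 823 between Gata1 and Eos, and 96 between Eos and Xbp1. The widest range was that of Xist, the RNA of the inactive X chromosome, at 4.74 ± 0.66 (SD, n = 2) in Eos wildtypes against 11.07 and 10.81 in the Xbp1 and Gata1 wildtypes. Lower in Gata1 wildtypes were Trim12a (5.83, against 9.91 and 9.94 in the Xbp1 and Eos lines), Nsg2 (6.06, against 9.58 and 9.62), Coro2a (6.45, against 9.73 and 9.90) and the lymphocyte surface protein Ly6e (9.55, against 12.38 and 12.32). Naip5 (4.64), Rny3 (10.40), Slc15a2 (5.02) and Atp5md (6.60) were also lowest there, while the protease Ctse (11.01, against 8.02 and 8.03) was highest. The count was 317 and 362 without Gata1 wildtype array 1 or 2, and 538 and 607 without Eos wildtype array 1 or 2.

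**Figure D5:**
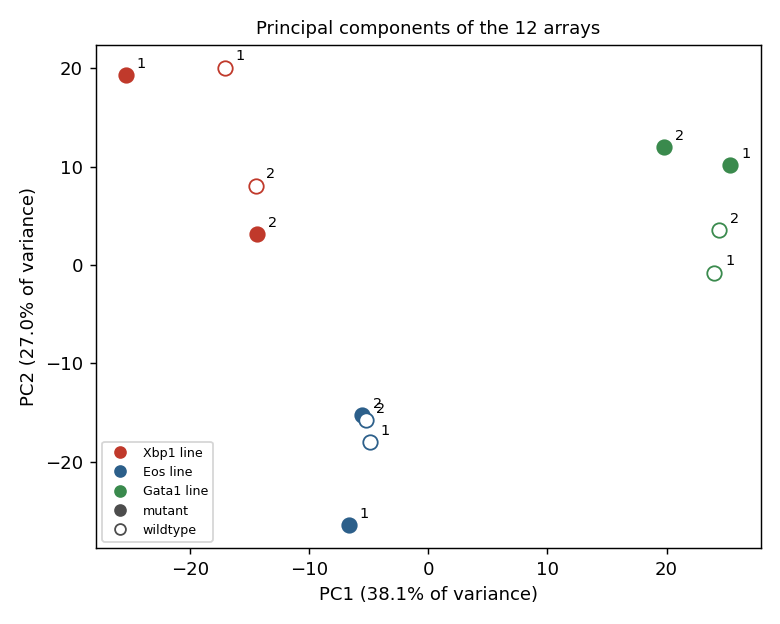
The 12 arrays on the first 2 principal components of the tested genes, with 38.1% and 27.0% of the variance on the x and y axes. Colours are lines, filled points mutants and open points wildtypes, and digits are replicate numbers. The lines lie apart, and the Xbp1 arrays split by number.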

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

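The tests of B cell genes outside the fixed list, of batch in the Xbp1 line and of the sex of the Eos line were chosen after the results they concern had been seen, as was the comparison of Gata1 wildtype arrays with the wildtype arrays of the other lines.

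B cell and class II genes were higher in Xbp1 mutant arrays, and the median difference in effect over the list was -0.54 for Eos minus Xbp1 and -0.46 for Gata1 minus Xbp1. The rise was not confined to the Xbp1 line. From wildtypes to mutants the list mean went from 6.91 to 7.56 there, from 6.83 to 6.95 in the Eos line and from 7.05 to 7.33 in the Gata1 line. An array batch in the Xbp1 line cannot be told apart from the genotype: the list's medians within the same-numbered pairs were 0.54 and 0.83, but a batch along the numbers cancels within pairs, and one along the genotype would look the same. B cells or their RNA in the sorted samples are a candidate source despite the exclusion of CD19: 14 of 15 other B cell genes were higher, with a median of 0.31 (bootstrap interval over genes 0.20 to 0.36) at percentile 100 of 10000 random lists of like level, although the change of 1 of the 15, Cd24a, was known when they were written down. Interval and percentile leave out the spread between arrays and the correlation among B cell genes. With an estimated correlation the fixed list lost its call. The rise was not particular to B cell genes: the mean of the myeloid list was 7.97 and 7.88 in the Xbp1 mutant arrays, against 7.22 and 7.77 in the wildtype arrays. Cd74 went from 8.72 to 9.53, H2-Aa from 8.03 to 8.90 and Cd79a from 7.33 to 8.40, while Ighm, which B cells transcribe strongly, changed by 0.25 ± 0.19. All 17 list members and all 15 others lay above the level filter in the mean of the Xbp1 wildtype arrays, and 0 are in another list. Tested genes had to reach that filter in their mean over all arrays, so the wildtype level was largely set by selection. It does not show that wildtype Tregs express these genes. A change within Tregs that follows the Xbp1 genotype stays open, since it was not tested.

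With the replicate block, 47 genes were called in the Gata1 line, led by Zhx2, whose effect exceeded that in the Xbp1 line by 1.84 and that in the Eos line by 1.73, and the count was 5 without both Gata1 arrays numbered 2, 23 with the block in the Xbp1 line only and 83 with the block and the Xbp1 line left out. Strain variants carried in the line may account for part of them, which was not settled. Of the 47, 22 had another called gene within 50 tested genes on the same chromosome. Random sets (10000) gave a median of 15 and a 95th percentile of 21 (permutation p = 0.043). The margin is narrow and includes the near-identical neighbours Olfr372 and Olfr373 and the adjacent Gm4951 and Iigp1. Random sets take no account of neighbours that change together for other reasons. Another genetic background in the Gata1 line cannot be told apart from a batch of that line or from an effect of the mutation: 59.6% of the called genes differed between the Gata1 wildtype arrays and the other lines' wildtype arrays, against 10.2% of other tested genes, but the same Gata1 wildtype arrays enter the call, and line, batch and background coincide. Zhx2, for which BALB/cJ mice are known to carry an allele of low expression, was at 7.08 in Gata1 wildtypes, against 8.81 in Gata1 mutants and 8.86 and 8.43 in Xbp1 and Eos wildtypes. The label is B6 throughout, and an effect of the Gata1 mutation itself stays open, since it was not tested apart from background.

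In all 4 Eos line arrays, Y-linked genes gave a signal in arrays labelled female, which lie below the level filter and so entered only the fits made without it. The mean of Kdm5d, Eif2s3y and Uty was 7.67 in the lowest Eos line array, 2.40 above the highest of the other 8 arrays, and Xist was at 4.27 to 5.20, against 10.46 to 11.46 elsewhere. Male mice in the Eos line, of both genotypes, are consistent with these values. A mixture of male and female cells is argued against, since the smallest gap in Xist between the other lines and the Eos line was 5.25. Sex and line therefore cannot be separated in comparisons of the Eos line with the others, while mutant and wildtype arrays within the line were alike in this respect.

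The other results are given as values. In Gata1 wildtype array 2 the mean of the same Y-linked genes was 5.27, with 4.24 or less in the other arrays outside the Eos line. Differences between lines passed camera with the preset correlation for several lists, B cell markers included, and each had an adjusted p of 0.896 to 0.939 with an estimated correlation. For the Eos minus the Xbp1 effect these were genes lower in Tregs (0.12), naive genes (0.18), the interferon response (-0.21) and myeloid markers (-0.27). For the Gata1 minus the Xbp1 effect they were the interferon response (0.30) and myeloid markers (-0.41), and for the Gata1 minus the Eos effect the interferon response (0.42) and immediate early genes (-0.16). Single arrays carry much of these: without Eos wildtype array 1 the Eos interferon median went from -0.25 to -0.05, without Eos mutant array 1 the Eos immediate early median went from 0.12 to 0.00, and with 1 array left out the Xbp1 medians ran from -0.33 to 0.13 for interferon, -0.30 to -0.03 for genes lower in Tregs, -0.26 to -0.05 for naive genes and 0.22 to 0.51 for myeloid markers.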

How the results depend on the processing

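Blocking without chosen arrays or in the Xbp1 line alone, leaving the Xbp1 line out, and leaving out single arrays for lists outside the Treg signature were chosen after seeing the data, and the causes of the changes below were not tested unless the setting itself changes the number of arrays or the threshold. Counts of called genes moved with several settings. With no level filter the Gata1 minus Xbp1 difference gave 3 genes. With every probe set as its own row the Gata1 minus Eos difference gave 0. Repeated quantile and cyclic loess normalisation each gave 5 genes for the Gata1 line and 2 for each of its differences from the other lines. The intensity trend gave 3 for Gata1 minus Xbp1 and 2 for Gata1 minus Eos. Array weights gave 1 for the Eos line, 10 for the Gata1 line, 6 for Gata1 minus Eos and 2792 for the wildtype groups. Fits of only 4 arrays gave 1 for the Eos line and 17 for the Gata1 line. An adjusted p under 0.1 gave 6 for the Gata1 line, 3 and 2 for its differences from the Xbp1 and Eos lines, and 3195 for the wildtype groups. An unadjusted p under 0.05 with a 1.5-fold change gave 45, 11 and 61 in the Xbp1, Eos and Gata1 lines, 3 for the mean effect, and 42, 339 and 186 for Eos minus Xbp1, Gata1 minus Xbp1 and Gata1 minus Eos. The replicate block gave 19, 1, 47, 18, 1, 74 and 27 in the same order, and with it the change in Ikzf4 in the Eos line (-0.96) passed, as it did with the Xbp1 line left out. Blocking in the Xbp1 line alone gave 11, 1, 23, 17, 1, 12 and 11. Leaving the Xbp1 line out gave 1 for the Eos line, 23 for the Gata1 line and 11 for Gata1 minus Eos, and with the block as well 1, 83 and 37. The block without both Gata1 arrays numbered 2 gave 5 for the Gata1 line, and without both Xbp1 arrays numbered 1 it gave 19 for the Xbp1 line. Leaving out 1 array at a time gave 0 to 15 genes for the Xbp1 line (15 without mutant array 1), 0 for the Eos line, 1 to 3 for the Gata1 line (1 without mutant array 2 or wildtype array 1), 0 to 12 for the mean effect (12 without Xbp1 mutant array 1), 0 to 2 for Eos minus Xbp1, 0 to 6 for Gata1 minus Xbp1, 0 for Gata1 minus Eos, and 317 to 1508 for the wildtype groups. Of the Treg signature tests, that of genes lower in Tregs in the Xbp1 line lost its call with an estimated correlation (0.929) and in both forms of fry (0.976 directional, 0.912 mixed), and ranged from 0.00155 to 0.543 with 1 array left out (0.543 without mutant array 1), while its median of -0.13 ran from -0.30 without mutant array 2 to -0.03 without mutant array 1. The change of Xbp1 in its own line (-0.45) ran from -0.85 without wildtype array 1 to -0.05 without wildtype array 2. Of the other lists, glycolysis in the Xbp1 line ranged from 3.41e-04 (without wildtype array 2) to 0.951 (without wildtype array 1, tested direction down). Immediate early genes in the Eos line ranged from 5.86e-06 (without mutant array 2) to 0.661 (without wildtype array 2), and turned down at 0.109 without mutant array 1. The interferon response in the Eos line was at 0.380 without wildtype array 1, and the erythroid list in the Xbp1 line at 0.980 without mutant array 2. B cell and myeloid markers in the Xbp1 line and the interferon and B cell lists in the Gata1 line kept their calls without any 1 array. With an estimated correlation all 12 lists called in the 3 lines lost their calls, these 4 included (0.383, 0.829, 0.929 and 0.929). All 12 lost them in directional fry too, with the lowest value, 0.217, for B cell markers in the Xbp1 line. In mixed fry 11 lost them and that list kept it at 0.0460. With no level filter 4 lost them: cell cycle (0.0641) and glycolysis (0.163) in the Xbp1 line, and immediate early genes and B cell markers in the Eos line (0.116 each). The correlation of fold changes between the Eos and Gata1 lines ran from -0.338 to 0.0557, turning positive without Eos mutant array 1. Over all settings, 617 list results kept their side of the threshold, 54 lost a call, 21 gained one and 2 turned the other way, and 675 gene results kept theirs, 17 lost a call and 42 gained one. Of the counts, 82 stayed within 1.5 times and 77 did not. What signal over background limits was not tested, since the deposited values hold no background measure.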

Other observations

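The tests over other splits of the arrays were planned, and the gene values and the comparison by replicate number were chosen after the data were seen.

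Some genes outside the lines' own comparisons differed between lines with the replicate block in limma. The IL-7 receptor Il7r changed by -0.56 in the Eos line and 0.34 in the Gata1 line, a difference of 0.90 (blocked adjusted p = 0.0359). The interferon-induced Usp18 and Ifit2 each differed by 0.96 between these lines (0.0359 for both), and these differences include the high Eos wildtype array 1, where Ifit2 was at 7.85, against 7.41 to 7.49 in the other 3 Eos line arrays, and Usp18 at 8.75, against 8.06 to 8.33. The neutrophil genes Lcn2 (-1.75, 0.0286), S100a9 (-1.54, 0.0402) and Camp (-0.86, 0.0449) had lower effects in the Gata1 than in the Xbp1 line, and Lcn2 and Camp were on none of the lists. The Xbp1 effects of Lcn2 and S100a9 rested largely on wildtype array 1, at 5.98 for Lcn2, against 7.14 to 7.65 in the other 3 arrays, and at 6.73 for S100a9, against 7.69 to 8.49. The complement component C1qb (0.65, 0.0417) and the lysosomal thiol reductase Ifi30 (0.62, 0.0454), which myeloid cells express, were higher in Xbp1 mutants with the block. The red cell gene Slc4a1 was higher by 1.18, 0.43 and 1.38 in the mutants of the Xbp1, Eos and Gata1 lines, and passed in the mean effect with the block (1.00, 0.0250) but in none of the 3 lines alone.

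Arrays numbered 1 and 2 differed in the Xbp1 line across both genotypes. In limma, 1539 of 11851 genes passed, 553 higher and 986 lower in the arrays numbered 1. Effector Treg genes were higher in them by a median of 0.12 (camera adjusted p = 1.23e-04), and interferon genes (-0.31) and B cell markers (-0.33) were lower, each with an adjusted p of 0.00677. With an estimated correlation all 3 had an adjusted p = 0.826.

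For the mean effect without a block, the real grouping gave 0 genes, so all 100 splits of the arrays within lines that were run, out of 108 possible, gave at least as many by construction, and their number says nothing about chance. The highest other split gave 1117 genes. That split parts the Xbp1 arrays by their number, which points to a structure of the samples, and 35 of the 100 splits gave at least 1 gene. With the block the real grouping gave 18 genes. Of the 32 splits that swap labels within pairs, 4 gave at least as many, the real one included. The highest other gave 89, so chance is not excluded there.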
